A study of Homo sapiens with 2 samples.

How the data were processed

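The series held 2 small-RNA sequencing libraries, replicate 1 and replicate 2 of a single group labelled TRACER. The labels do not say what that word stands for, and its meaning is not assumed here. Both came from HEK293T cells, an established human embryonic kidney line. Per the labels, the cells received doxycycline at 3 ug/mL for 24 hours, RNA was taken from the cytoplasm with Trizol, and a Qiagen microRNA library protocol was used. Doxycycline is a drug commonly used to switch on an introduced gene, but the labels name no such gene. The labels give no untreated, input or control library, so no comparison between conditions could be made. They do not say whether the replicates were separate cultures, so the spread between them may be technical only. The library name of replicate 1 carries the number 3 and that of replicate 2 the number 2, and the replicate numbers of the sample titles were used.

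The files held 1 list of RNA peaks per library, so the authors called peaks in each library on its own and did not pool them. Per the submitters' processing notes, the tools were cutadapt 4.2, UMI-tools 1.1.4 and STAR 2.7.11 with the GRCh38 genome build, with no role or order given. Per the names of the deposited files, the peaks came from CLIPper and the reads had passed a filter on alignment score, mismatches and number of loci. The CLIPper version and its gene annotation are not given in the sources used here. The deposited score column held a p-value per peak as CLIPper writes it, with no adjustment stated, and every one of them was under 0.05. Each peak name held a gene identifier, a peak number and a whole number of reads, which is not normalised, and its smallest value was 3. The thick interval of each peak marked its summit and spanned 4 nt in 94.1% of peaks. A read can be counted in several neighbouring peaks, under several gene entries and at several loci, so sums of reads are sums over peaks and not sequencing depth. The total number of sequenced or mapped reads is not known from these files.

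Gene models came from GENCODE release 29 on GRCh38, and positions of ribosomal RNA genes from a RefSeq gene table of the same build. Of the 20048 gene identifiers in the peak lists, 19811 were found in that annotation. Transcript sequences were used for all sequence work. Coordinates are 1-based on GRCh38. Peaks with the same position listed under several genes were counted once, except in values per gene, where each gene entry kept its reads. A summit was the middle of the thick interval. It was assigned on the same strand to the 3′ UTR, coding sequence (CDS), 5′ UTR, non-coding exon, intron or none of these, in that order of priority. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

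Overlap between libraries was the percent of peaks that shared at least 1 nt with a peak of the other library on the same strand, with an exact 95% binomial interval. Its chance level came from 100 placements of each peak at random within the unbroken annotated stretch of the gene's region that held its summit. Peaks without such a stretch or wider than it were not placed, which left 95337 peaks in replicate 1 and 103720 in replicate 2. Gene signal was correlated across genes as log2(reads in peaks + 1), without a p-value, since genes are not independent replicates. The expected number of summits per region spread the exonic summits of each protein-coding gene evenly over its exonic length, and 95% intervals came from 1000 bootstrap draws of genes. Positions within the 3′ UTR of 1 representative transcript per gene were set beside 100 random placements.

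A list of 24 sequence motifs was searched in a window of 51 nt around 1 summit per gene, the one with the most reads. Each was compared with 1 random window of the same 3′ UTR outside all peaks of that library. The test was McNemar's exact two-sided test over genes, with Benjamini-Hochberg adjustment over the 48 tests of both libraries. A motif was called when the adjusted p was under 0.05 in both libraries in the same direction. These p-values describe each library, since genes are not replicates. A mean ratio of a motif is the geometric mean over both libraries. Base composition was compared in the same windows. At CDS summits, windows of 17 codons in frame were compared with a control window of the same CDS, using bootstrap intervals and an exact two-sided sign test over genes.

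For each of 18 gene lists, the median percent of peak reads in the 3′ UTR was taken over protein-coding members with at least 10 peak reads. It was ranked among 10000 random lists of the same size matched on deciles of summed peak reads, and a list with fewer than 3 such members was not ranked. The genes named in the text are the 10 with the largest mean percent of peak reads, and the 10 protein-coding genes with the most 3′ UTR peaks found in both libraries. Also named are the 3 members of each list with the most reads, every CCR4-NOT subunit with a peak in both libraries, and the 5 peaks found in both libraries with the lowest p-values. Some genes that these rules select are not reported. Tests, motifs, gene lists, naming rules and most alternatives were chosen before the data were examined. The alternatives were a stricter p-value of 1e-05, a minimum of 20 reads per peak, 50% reciprocal overlap, only peaks found in both libraries, each library alone, and other pseudocounts, minimum reads, weights, region orders, summit definitions, window lengths and control windows.

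Further alternatives were chosen after seeing the data. These were region lengths from 1 representative transcript, gene lists corrected for UTR length or without genes that lack an annotated 3′ UTR, overlap and correlation over exons of coding genes only, control windows 100 nt downstream, and 20 other draws of the control window. The list of all hexamers, the share of motif sites under peaks, the regions with the most reads, the reading-frame comparison and the comparison of coding and untranslated reads per gene were also added after the first results.

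The procedures were tested on simulated data. With summits placed at random in 10715 genes, the observed over expected ratios were 0.997 for 3′ UTRs, 1.00 for CDS and 1.00 for 5′ UTRs, and 0 motifs were called. The arginine codon difference of that simulation was 0.134 percentage points with an interval of 0.00622 to 0.268. In 10 further random libraries this difference averaged -0.0172, and 0 of the 10 intervals left out 0. In 200 genes a summit was placed on an existing Pumilio element and given more reads than any other summit of its gene. By construction 100% of those genes were seen, so this says nothing about sensitivity. The ratios were 3.32 and 3.23, which was called. Of 200 random lists of 25 genes, 0.5% ranked at or above the 97.5th percentile and 3% at or below the 2.5th, and a list raised by 30 percentage points ranked at 100. Intervals on counts cover counting error only.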

Results

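The data were peaks of cytoplasmic RNA from doxycycline-treated HEK293T cells, in 2 libraries of the single TRACER group. The stated aim of the series was to find RNA elements that associate with CCR4-NOT, the main complex that removes poly(A) tails from messenger RNA. Replicate 1 held 96682 distinct peaks with 1585443 reads summed over them, and replicate 2 held 105125 peaks with 1663899 reads. The median peak was 27 nt wide in replicate 1 and 28 nt in replicate 2, and the median peak held 6 reads in each. Peaks fell in 18035 genes in replicate 1 and 18089 in replicate 2, of which 12237 and 12327 were protein-coding. The CLIPper p-value was at or under 1e-05 for 33.7% and 36.3% of peaks. Unless stated otherwise, errors are the SD over the 2 libraries.

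The first comparison asked how far the peaks repeated between the libraries. Of the peaks of replicate 1, 60.6% (exact 95% interval 60.2 to 60.9) overlapped a peak of replicate 2. In the other direction the share was 55.9% (55.6 to 56.2). Random placement within the same unbroken annotated stretch of the gene gave 30.4% and 28.2%. Overlap rose with the reads in a peak. It was 33.7% and 27.7% for peaks of 3 to 4 reads, and 98.6% and 99.0% for peaks of 50 reads or more. Of 136609 regions merged over both libraries, 52983 held a peak in each, of which 12143 lay in 3′ UTRs and 26268 in CDS. Across 20048 genes, log2(reads + 1) correlated with a Pearson coefficient of 0.842 (bootstrap 95% interval 0.838 to 0.846) and a Spearman coefficient of 0.906 (0.903 to 0.909). Genes are not independent replicates. Peaks were found in both libraries for 16076 genes, in replicate 1 only for 1959 and in replicate 2 only for 2013, and the genes found in 1 library had a median of 4 reads.

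**Figure D1:**
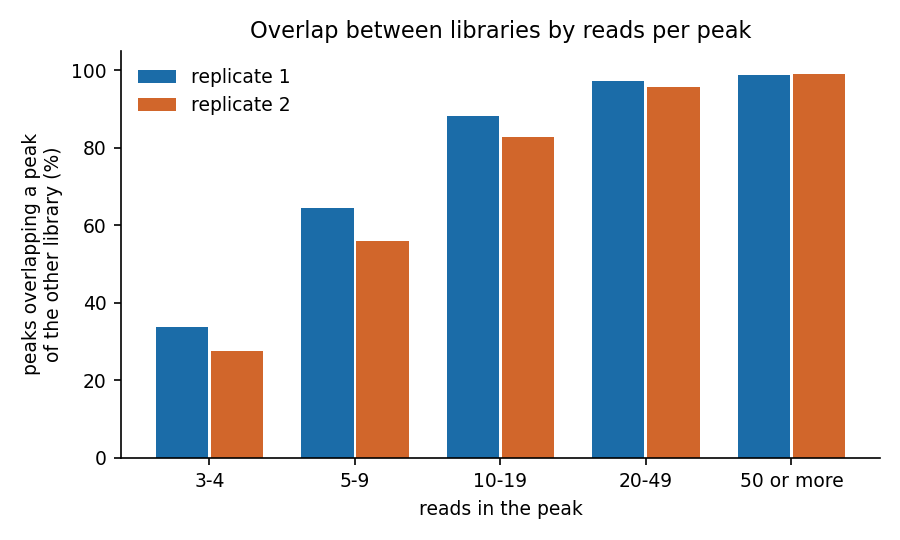
Percent of peaks in each library that overlapped a peak of the other library (bars, vertical axis in percent), by the number of reads in the peak. The share rose from 33.7% and 27.7% at 3 to 4 reads to 98.6% and 99.0% at 50 reads or more.

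Protein-coding genes held 58.0% ± 3.598 (SD, n = 2) of peak reads and 87.8% ± 0.549 of peaks. Nuclear ribosomal RNA held 23.7% ± 1.07 of reads in 0.159% ± 0.0178 of peaks. Pseudogenes held 7.31% ± 0.465 of reads, the mitochondrial genome 3.72% ± 1.54, long non-coding RNA genes 3.16% ± 0.0352, small nucleolar and Cajal body RNA genes 1.14% ± 0.213, spliceosomal snRNA genes 0.564% ± 0.0804 and other small RNA genes 1.71% ± 0.141. MicroRNA genes held 0.170% ± 0.0108 of reads, although the library protocol was made for microRNAs. The microRNA genes with the most reads were MIR6723 with 72 and 45 reads in replicates 1 and 2, MIR221 with 55 and 61, and MIR222 with 67 and 48. MIR6723 lies within the stretch of AL669831.3 on chromosome 1, 629301 to 634785, on the same strand, and 74.9% and 73.6% of the reads of that gene entry lay on mitochondrial pseudogenes annotated on the other strand.

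The gene entries with the largest share of peak reads were FP236383.1 (ENSG00000280441) with 12.1% ± 0.682 and FP671120.1 (ENSG00000278996) with 10.6% ± 0.328. Both are annotated as long non-coding RNAs on chromosome 21, and their peaks lay on copies of the ribosomal RNA genes in the RefSeq table. The 5 peaks found in both libraries that led by lowest deposited p-value, which was listed as 0, and then by reads were all there. The strongest, on RNA28SN2 at chromosome 21, 8218410 to 8218495, held 12122 and 13914 reads. One on RNA28SN3 at 8401448 to 8401525 held 12118 and 13919 reads, so reads at these near-identical copies cannot be assigned to 1 copy. The other three, also on RNA28SN3, adjoined each other from 8401605 to 8401653 and held from 9339 to 12934 reads. MT-RNR2 held 1.33% ± 0.529 and MT-RNR1 0.725% ± 0.244. Other leading entries were MT-CO1 with 0.326% ± 0.173, AL669831.3 with 0.279% ± 0.129, AL627171.2 with 0.273% ± 0.00460, RN7SL2 with 0.258% ± 0.0753 and HNRNPA2B1 with 0.257% ± 0.0203. AL627171.2 and RN7SL2 overlap on the same strand, so their reads cannot be told apart.

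The second comparison asked where peaks lay within transcripts. CDS held 50.2% ± 1.71 of summits, 3′ UTRs 22.8% ± 0.385, non-coding exons 11.3% ± 0.319, introns 8.13% ± 1.02 and 5′ UTRs 6.92% ± 0.0321. Weighted by reads, the mean shares were 34.6%, 14.1%, 15.8%, 29.3% and 4.97% in the same order. Ribosomal RNA enters these values, since the named peaks on RNA28SN2 and RNA28SN3 were classed as introns of FP671120.1 and FP236383.1. Nuclear ribosomal RNA held 23.7% of all peak reads, so the 29.3% cannot be read as signal from introns of protein-coding genes. Relative to the length of each region in the same genes, CDS summits were more frequent than an even spread. The ratio was 1.43 (1.41 to 1.44) in replicate 1 over 10715 genes and 1.45 (1.44 to 1.47) in replicate 2 over 11023 genes. In 3′ UTRs the ratio was 0.650 (0.640 to 0.659) and 0.622 (0.613 to 0.630), and in 5′ UTRs 0.759 (0.736 to 0.780) and 0.751 (0.731 to 0.773). Within 3′ UTRs, the median summit lay at 0.402 and 0.400 of the way from the stop codon to the transcript end, against 0.499 and 0.499 for random placement. The median distance to the transcript end was 961 and 953 nt, against 853 and 856 nt at random.

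**Figure D2:**
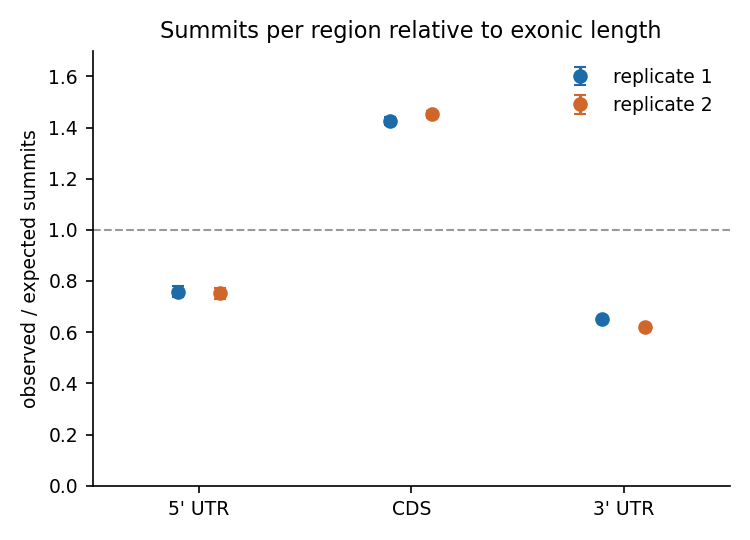
Observed over expected number of summits in 5′ UTRs, CDS and 3′ UTRs of protein-coding genes (vertical axis, a ratio without unit), with an even spread over exonic length as the expectation. Points are libraries, bars are bootstrap 95% intervals over genes, and the dashed line marks 1; CDS lay at 1.43 and 1.45 and 3′ UTRs at 0.650 and 0.622.

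The third comparison asked which of 24 sequence motifs were more or less frequent at 3′ UTR summits than elsewhere in the same UTR. It covered 6570 genes in replicate 1 and 6765 in replicate 2. The Pumilio element UGUANAUA, the binding site of Pumilio proteins, occurred in 6.94% of summit windows and 0.944% of control windows in replicate 1. In that library 447 genes had it only at the summit and 53 only in the control, a ratio of 8.43 (6.33 to 11.4), with an adjusted p of 2.48e-77 by McNemar's exact test. In replicate 2 it occurred in 7.63% against 0.872%, a ratio of 9.96 (7.46 to 13.6) with an adjusted p of 4.55e-94 by the same exact test. The size of the geometric mean ratio, 9.17, depended on the windows compared: it was 4.27 against windows 100 nt downstream, 5.11 against windows 100 nt upstream, 5.56 over all summits and 13.8 for peaks found in both libraries.

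Another 5 motifs were more frequent at summits in both libraries. The miR-101 site had ratios of 4.94 and 6.14, the miR-92 family site 3.69 and 2.46, the GU repeat UGUGUGU 2.93 and 2.97, the miR-17 family site 2.18 and 2.24, and the reversed Pumilio element AUANAUGU 2.07 and 2.02. The reversed element was included as a control of the same composition, and its intervals, up to 3.02 in replicate 1, lay below those of the Pumilio element. They overlapped those of the miR-92 and miR-17 sites and the GU repeat in both libraries. For the miR-101 site they overlapped in replicate 1 only. Less frequent motifs were the C-rich element CCUCCC with ratios of 0.197 and 0.221, the miR-122 site with 0.0769 and 0.263, and the miR-1 site with 0.370 and 0.355. Over 20 other draws of the control windows, the Pumilio element, the miR-101 and miR-92 sites, the GU repeat and the reversed Pumilio element were called more frequent in 20, the miR-17 site in 18, the C-rich element less frequent in 20, the miR-122 site in 16, and the miR-1 site in only 3. Against windows 100 nt downstream the miR-101 site and the reversed Pumilio element were not called, with mean ratios of 2.25 and 1.31, and the miR-17 site was not called at p at or under 1e-05. Mean ratios of both libraries over all settings ranged from 2.25 to 5.51 for the miR-101 site, from 2.03 to 3.81 for the miR-92 site, from 1.599 to 4.46 for the GU repeat and from 1.52 to 5.94 for the miR-17 site. Against shuffles of the same windows none of these 3 less frequent motifs was called, and with longer windows or windows 100 nt downstream only the C-rich element was. The remaining 15 motifs were not called, among them AU-rich elements of 3 lengths, the m6A consensus DRACH, the poly(A) signal AAUAAA and the let-7, miR-21 and miR-16 sites. The miR-16 site was called more frequent against shuffled windows, with a mean ratio of 1.76. The G4-like motif GGGNNNGGG had ratios of 1.09 (0.891 to 1.33) and 1.37 (1.13 to 1.66), past the threshold in replicate 2 only. It was called more frequent in 3 of the 20 other draws, against shuffled windows and over all summits. The ARE pentamer AUUUA had ratios of 0.943 (0.837 to 1.06) and 0.985 (0.876 to 1.11). The ARE heptamer UAUUUAU had 1.14 (0.872 to 1.503) and 1.598 (1.21 to 2.11), past the threshold in replicate 2 only, and was called more frequent in 4 of the 20 other draws, against shuffled windows and with longer windows. The miR-19 site had 1.28 (0.827 to 2.001) and 2.14 (1.26 to 3.72), past the threshold in replicate 2 only, and was called more frequent in 4 draws, against shuffled windows, with longer windows and over all summits. The Quaking element ACUAAY had 0.691 (0.496 to 0.959) and 0.7 (0.508 to 0.960), with an adjusted p of 0.0521 by the exact test in each library, and was called less frequent in 9 draws, for peaks found in both libraries and against shuffled and downstream windows.

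**Figure D3:**
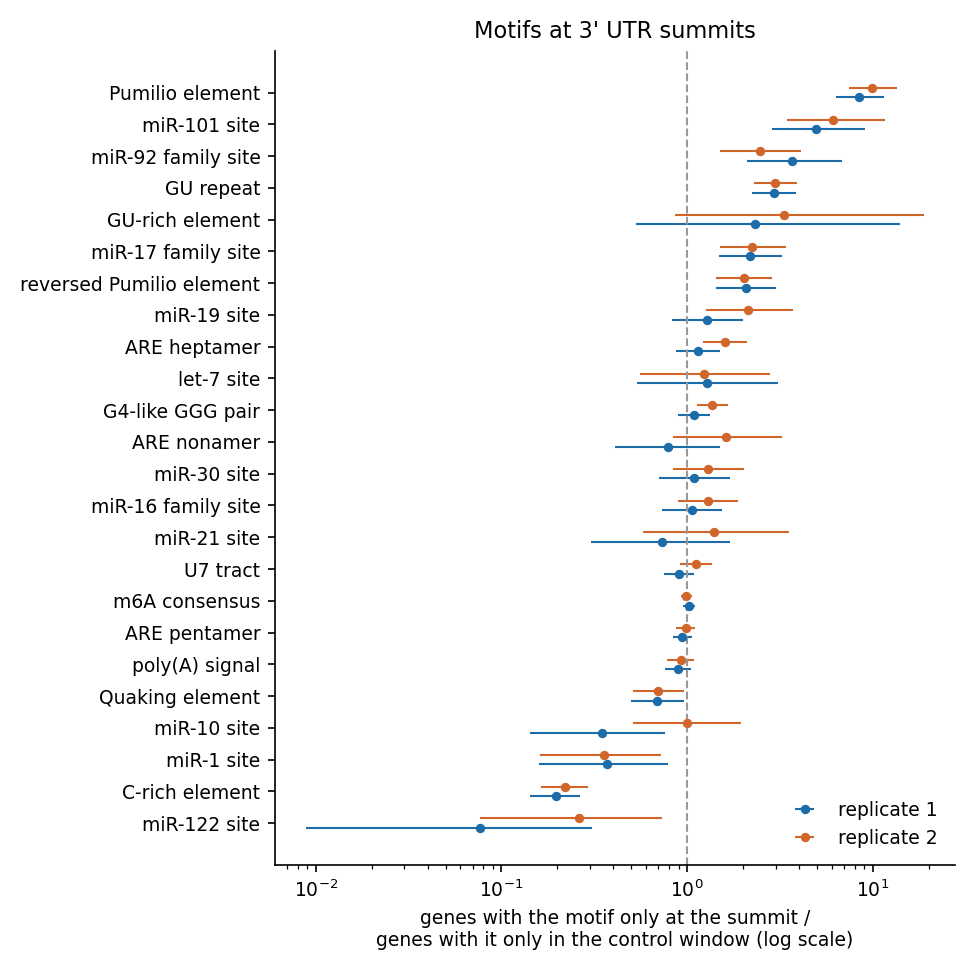
Number of genes with a motif only at the summit divided by the number with it only in the control window (horizontal axis, log scale, no unit), for 24 motifs in both libraries. Points are ratios, bars are exact 95% intervals and the dashed line marks 1; the Pumilio element had the highest ratios, 8.43 and 9.96.

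The 3′ UTRs of 6121 genes held 3778 Pumilio elements, and 805 of them (21.3%, exact 95% interval 20.01 to 22.65) lay under peaks of both libraries, against 2.62% of all bases of these UTRs. By the base at the variable position, the share was 31.2% for UGUAGAUA, 23.1% for UGUAAAUA, 20.3% for UGUACAUA and 16.97% for UGUAUAUA. It was 12.8% for miR-101 sites, 8.57% for miR-92 sites, 5.67% for the reversed Pumilio element, 2.25% for the ARE pentamer, 3.69% (exact 95% interval 3.15 to 4.28) for the ARE heptamer and 0.292% for the C-rich element. Of 2317 genes with a Pumilio element, 709 had at least 1 under peaks of both libraries. Elements were most frequent from 10 nt before to 9 nt after the summit. In replicate 1 there were 30.8 elements per 1000 windows that began from 0 to 9 nt after the summit, against 2.77 and 4.33 in the outermost bins, 81 to 90 nt before and 80 to 89 nt after it. In replicate 2 the values were 31.2 against 4.04 and 4.55. Among all 4096 hexamers, 595 were more and 845 less frequent at summits in both libraries, and 10 of the 20 leading ones held UGUA. The leading hexamer was UGUAGA, with ratios of 9.10 and 6.29.

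**Figure D4:**
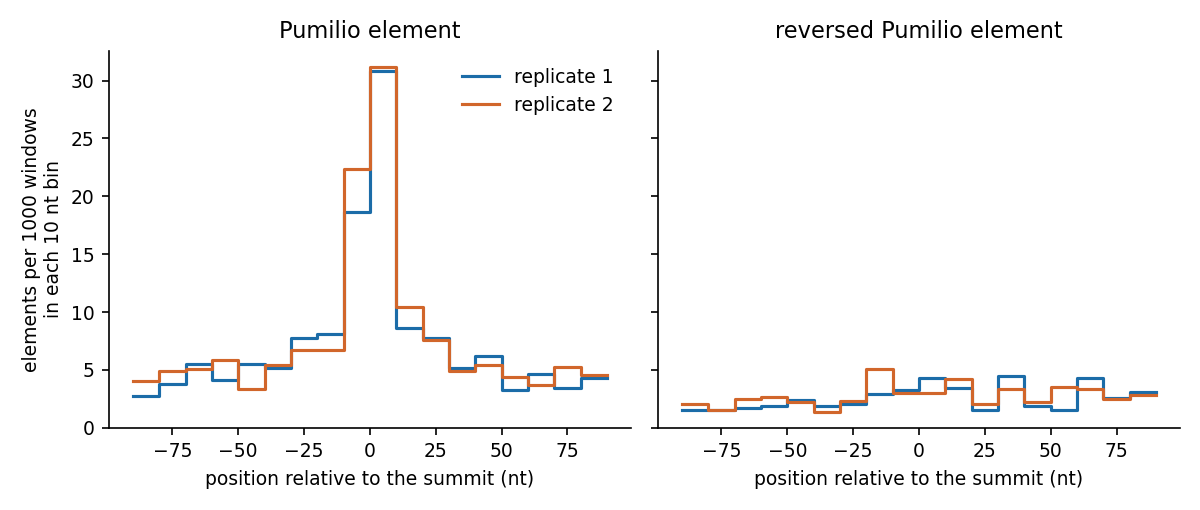
Number of Pumilio elements (left) and reversed Pumilio elements (right) per 1000 summit windows in bins of 10 nt (vertical axis), by the position of their first base relative to the 3′ UTR summit in nt (horizontal axis). Lines are libraries; the Pumilio element reached 30.8 per 1000 windows in replicate 1 in the bin from 0 to 9 nt.

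Several 3′ UTR peaks illustrate these sites. The strongest 3′ UTR region of SLC38A2 found in both libraries (chromosome 12, 46358651 to 46358744, minus strand) held up to 183 and 212 reads. Its summit window, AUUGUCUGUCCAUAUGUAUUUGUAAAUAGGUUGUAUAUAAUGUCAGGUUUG, held 2 Pumilio elements and lay 2406 nt after the stop codon. In CNOT8, which encodes a deadenylase of CCR4-NOT, the strongest region (chromosome 5, 154875885 to 154875941, plus strand) held up to 29 and 42 reads and its window held UGUAGAUA. In CNOT1, which encodes the scaffold of the complex, the region on chromosome 16 from 58520698 to 58520757, minus strand, held up to 41 and 84 reads and its window held UGUAAAUA. The corresponding windows of PUM2, BTG1, JUN, SOX4, E2F3 and CDKN1B held 0 elements. So did those of CNOT2, CNOT6, CNOT6L, CNOT9 and CNOT11, the other CCR4-NOT subunits with a 3′ UTR peak in both libraries. NORAD, a long non-coding RNA that binds Pumilio proteins, held 15 elements, 7 of them under peaks of both libraries, while 14.5% of its bases lay under such peaks.

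The fourth comparison asked which kinds of genes carried their signal in the 3′ UTR. The median percent of peak reads in the 3′ UTR was 51.9% ± 4.38 for 26 and 27 genes of CCR4-NOT adaptors, proteins that bring the complex to RNA. Matched random lists had medians of 20.9% and 20%, and the percentiles were 100 and 99.98. For 30 and 31 immediate early and AU-rich element genes the median was 56.9% ± 6.66, with percentiles of 100 and 99.99. For 5 Pumilio target genes it was 67.2% ± 6.74, with percentiles of 99.7 and 99.0. After subtraction of the UTR's share of each gene's length, the adaptors and the immediate early genes stayed at 99.97 or above in each library, and the Pumilio targets fell to 65.4 and 26.2. Cytosolic ribosomal protein genes had a median of 2.49% ± 0.637 and nuclear-encoded oxidative phosphorylation genes 5.66% ± 0.701, both at percentile 0 in both libraries, and at 0.07 or below after that subtraction.

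CCR4-NOT subunits had a median of 15.2% ± 0.908 at percentiles of 34.7 and 31.5, and of 87.3 and 86.05 after subtraction of the UTR's share of length. Other decay factors had 32.0% ± 0.515 at 90.2 and 92.2, and 84.98 and 87.8 after it. C2H2 zinc finger genes had 26.7% ± 3.59 at 99.5 and 95.6, and fell to 21.65 and 15.1 after it. Abundant housekeeping genes had 7.04% ± 2.32 at 19.005 and 4.64, cell cycle genes 15.4% ± 3.36 at 38.7 and 17.2, and unfolded protein and integrated stress response genes 19.2% ± 2.68 at 52.5 and 72.3. After the subtraction these 3 lists stood at 80.4 and 72.4, at 98.9 and 91.96, and at 97.55 and 97.4. Replication-dependent histones had a median of 0%, at percentile 0 in both libraries, and 33 of the 68 coding members in the peak lists have no annotated 3′ UTR. Without such genes the mean percentile was 0.0075, and after the subtraction the percentiles were 89.4 and 91.8. In that subtraction a gene without an annotated 3′ UTR has a difference of 0 by construction, above the random medians of -16.2 and -17.1. These percentiles are therefore partly set by the annotation, and the subtraction was not repeated without such genes. The 13 coding genes of the mitochondrial genome have no annotated 3′ UTR, which makes their percentiles of 0.855 and 0.665 void. Interferon response genes and genes restricted to other tissues had too few scored members, and held 0.00602% ± 0.00251 and 0.00117% ± 2.66e-06 of peak reads. The lists of microRNA, small nucleolar and other abundant small RNA genes have no 3′ UTRs, and held 0.168% ± 0.0112, 1.12% ± 0.189 and 1.40% ± 0.130.

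**Figure D5:**
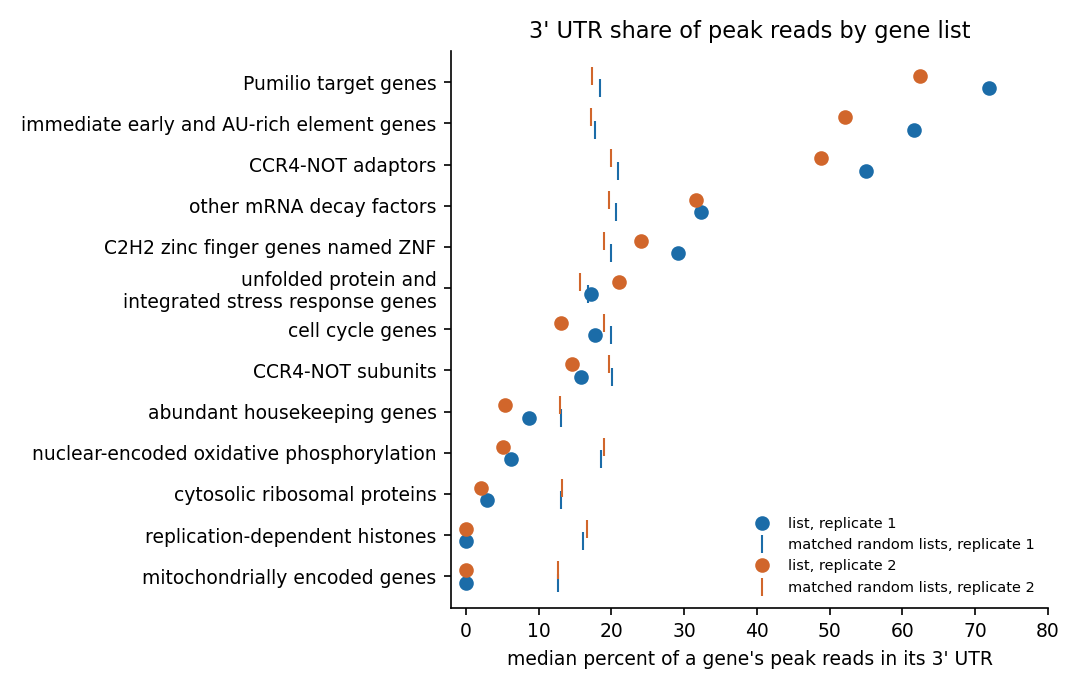
Median percent of a gene's peak reads in its 3′ UTR (horizontal axis) for 13 gene lists in both libraries (circles), beside the median of 10000 matched random lists (vertical ticks). CCR4-NOT adaptors lay at 55.0% and 48.8% against 20.9% and 20% for random lists; the histone and mitochondrial lists include genes without an annotated 3′ UTR.

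Each of the 12 CCR4-NOT subunits had at least 1 peak found in both libraries, and 7 had such a peak in the 3′ UTR. CNOT7 (ENSG00000198791), which encodes a deadenylase, had the most reads, 1374 and 1675, in 15 peaks found in both libraries. Of its exonic reads, 9 in replicate 1 and 0 in replicate 2 lay in untranslated regions, and peaks covered 88.7% and 96.2% of its 858 nt of CDS. CNOT1 had 790 and 1632 reads, a larger difference between libraries than that of all peak reads, and 5.75% ± 0.793 of them in the 3′ UTR. TNKS1BP1 had 218 ± 117 reads with 0% in the 3′ UTR in both libraries. The 9 other subunits ranged from CNOT3 with 10 and 7 reads to CNOT6 with 196 and 190. Of these, CNOT6L had the highest 3′ UTR share, 97.53% ± 3.49, followed by CNOT6 with 63.6% ± 8.13, CNOT11 with 46.4% ± 5.05, CNOT8 with 45.03% ± 2.65, CNOT9 with 38.2% ± 9.33, CNOT2 with 20.5% ± 8.42 and CNOT4 with 4.17% ± 5.89. CNOT3 and CNOT10 had 0% in both libraries.

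The genes with the most 3′ UTR peaks found in both libraries were GNAS with 19, MARS with 15, NUCKS1, SCD and CREB3L2 with 13 each, PANK3, IREB2, TNPO1 and ACVR2B with 12 each, and SOX4 with 11. Of their peak reads, between 38.4% ± 0.742 in NUCKS1 and 80.3% ± 3.15 in ACVR2B lay in the 3′ UTR. Among the adaptors, PUM2 had 90.02% ± 5.85 and BTG1 60.6% ± 4.99 of its reads there. Other members with a large 3′ UTR share were E2F3 with 98.5% ± 2.14, CDKN1B with 73.3% ± 14.04, ZNF703 with 70.04% ± 9.76, SLC38A2 with 62.7% ± 2.72, ZNF146 with 60.1% ± 5.57, DDIT4 with 56.8% ± 7.25, DDX6 with 53.4% ± 0.164, JUN with 48.1% ± 6.95 and ATF4 with 46.7% ± 1.23. In these values a base counted as 3′ UTR if any annotated coding transcript placed it there, even where another transcript codes. The values per gene, such as the 19 peaks of GNAS, were not repeated with CDS given priority and may include coding sequence.

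At the other end, RPS3 had 3.23% ± 0.0674, RPL3 2.25% ± 0.440, ATP5F1B 5.36% ± 1.695, CALR 5.40% ± 3.22, PABPC1 5.93% ± 0.407 and TUBA1B 0.893% ± 1.26, while RPL8, ENO1, ATP5F1A and MCM7 had 0% in both libraries. Between these lay ACTG1 with 28.2% ± 1.23, ATP5IF1 with 32.9% ± 0.488, DIS3 with 17.9% ± 2.13, PCNA with 12.7% ± 0.846 and MCM2 with 10.6% ± 0.963. Histone genes HIST2H2BE, HIST2H3A and HIST2H3C held 0.162% ± 0.0240, 0.102% ± 0.00314 and 0.101% ± 0.00599 of peak reads, and small RNA genes RN7SL1, RPPH1, SNORD3A, SNORD3B-2 and SNORD3B-1 held 0.218% ± 0.0304, 0.151% ± 0.00781, 0.137% ± 0.0265, 0.101% ± 0.0167 and 0.0987% ± 0.0170. The values of the HIST2H3, SNORD3 and RN7SL genes are uncertain because near-identical copies can share reads. The ZNF503 entry with the most reads, 249 and 470, was a long non-coding RNA gene listed under that symbol. IFI6 had 5 and 7 reads, IFIT1 0 and 11, CKM 15 and 11, and GFAP 0 and 3.

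The last comparison concerned base and codon content. In 3′ UTR windows, C fell by 6.94 percentage points (bootstrap 95% interval -7.23 to -6.68) at summits relative to control windows in replicate 1, from 22.1% to 15.2%. In replicate 2 it fell by 6.98 points (-7.24 to -6.70). G was higher by 4.56 (4.33 to 4.82) and 4.67 (4.41 to 4.92) points and U by 2.49 (2.17 to 2.80) and 2.72 (2.38 to 3.03), while A differed by -0.119 (-0.404 to 0.152) and -0.411 (-0.677 to -0.130). With longer windows the mean difference in G was 2.18 in place of 4.62 points, and that in A was 0.109 in place of -0.265. In CDS windows, C differed by -6.53 and -6.44 points and U by -1.67 (-1.85 to -1.47) and -2.14 (-2.33 to -1.94), while G was higher by 6.96 and 7.82 and A by 1.24 and 0.763. In non-coding RNA genes U differed by -1.74 and -2.62 points.

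The codons CGG, CGA and AGG made up 4.18% of codons at CDS summits and 2.90% in control windows in replicate 1, a difference of 1.27 points (1.14 to 1.40) over 9146 genes. The share was higher at the summit in 3145 genes and lower in 2000, with an adjusted p of 2.98e-57 by the exact sign test. In replicate 2 the shares were 4.34% and 2.93%, a difference of 1.41 points (1.28 to 1.55) with an adjusted p of 2.42e-71 by the same exact test. All 6 arginine codons together differed by 1.46 and 1.61 points, although CGC alone differed by -0.278 and -0.243 points. The same 3 triplets were also more frequent out of frame, by 2.33 and 2.73 points at 1 base after the codon start and by 1.05 and 1.16 points at 2 bases. G or C at the third codon position was higher by 0.627 (0.186 to 1.07) and 1.67 (1.24 to 2.11) points, and the adjusted p of the exact sign test was 0.0499 and 1.21e-05. In windows of 9 codons the mean difference was 2.48 in place of 1.15 points.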

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

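The signals listed here were picked out because they lie in parts of the peak lists that the comparisons of regions, motifs and gene lists did not use. No control library exists to set them against, and no explanation was tested. Peaks under gene identifiers absent from the annotation numbered 353 in replicate 1 and 372 in replicate 2, which is 0.365% and 0.354% of all peaks. The largest held 1849 and 1872 reads, and 70.8% and 65.6% of them overlapped a peak of the other library, against 60.6% and 55.9% of all peaks. Peaks whose summit lay outside the exons and introns of the gene they were listed under numbered 303 in replicate 1 and 319 in replicate 2, or 0.313% and 0.303% of all peaks. Of these, 73.9% and 72.1% overlapped a peak of the other library, and the largest held 247 and 257 reads.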

How the results depend on the processing

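No paired analysis was possible because the series has a single group. Each setting was changed alone, and the added settings named in the methods were chosen after seeing the data. The cause of a change was not tested unless stated.

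The region ratios stayed on the same side of 1 under every setting tried. Overlap between libraries was 44.1% with 50% reciprocal overlap, 71.3% for peaks with p at or under 1e-05 and 78.4% for peaks of at least 20 reads, where chance gave 11.8%, 38.8% and 44.13%, against 58.2% and 29.3% by chance in the main setting. The Pearson and Spearman correlations were 0.671 and 0.837 at p at or under 1e-05, 0.933 and 0.915 for genes with at least 10 reads in each library, and 0.860 and 0.931 for exons of coding genes. A pseudocount of 10 gave a Pearson coefficient of 0.946. Counting peaks in place of reads, coding genes held 87.8% and nuclear ribosomal RNA 0.159%, by construction, since few ribosomal peaks hold many reads. The 3′ UTR share of summits was 21.9% for peaks found in both libraries, 21.2% with CDS given priority and 14.1% weighted by reads, where the CDS share was 34.6%. Ribosomal RNA peaks were part of the total in that weighting. The median 3′ UTR position was 0.397 at p at or under 1e-05, 0.404 for peaks found in both libraries and 0.404 with 1 summit per gene.

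The main setting called 6 motifs more and 3 less frequent. The counts were 11 and 1 against shuffled windows, 10 and 1 with the longer windows, and 4 and 5 against windows 100 nt downstream. Over 20 other draws of the control windows, the fewest called less frequent was 1. The Pumilio element, the GU repeat and the miR-92 site were called more frequent under every setting tried, with Pumilio ratios from 4.27 to 13.8. The miR-17 site was not called at p at or under 1e-05, although its mean ratio was 2.54 there against 2.21 in the main setting. The miR-101 site and the reversed Pumilio element were not called against downstream windows, where their ratios were 2.25 and 1.31. Of the 3 motifs called less frequent, none was called against shuffled windows, and only the C-rich element was called with the longer windows and against downstream windows. The miR-1 site was also not called at p at or under 1e-05, for peaks found in both libraries or over all summits. Its mean ratios there were 0.492, 0.330 and 0.545, against 0.363 in the main setting, so the direction stayed the same. Counting motifs called in the main setting or in the changed one, ratios that crossed 1 were those of the C-rich element (1.34), the miR-1 site (2.62) and the poly(A) signal (1.95) against shuffled windows, and the poly(A) signal (1.75) and m6A consensus (0.913) against windows 100 nt upstream. The others were the U7 tract (0.634) against downstream windows, the ARE pentamer (1.25) with the longer windows and the miR-21 site (0.565) over all summits. Of the remaining results for single motifs, 176 kept their call or lack of one, some of them uncalled with a ratio that crossed 1, 21 gained a call and 11 lost one.

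The difference in A at 3′ UTR summits was -0.579 points at p at or under 1e-05, and each library alone gave -0.411 to -0.119, of which the value of replicate 2 excluded 0. With the longer windows it was 0.109. The difference in G or C at the third codon position was 1.05 points at p at or under 1e-05 and 0.756 for peaks found in both libraries, where it was no longer past the threshold in both libraries, and 2.48 with windows of 9 codons.

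With the UTR's share of gene length subtracted, the mean percentile of Pumilio targets was 45.8, of histones 90.6 and of mitochondrial genes 99.6. The last came from members that lack an annotated 3′ UTR, as do 33 of the 68 coding histones. Such members have a difference of 0 by construction. Lists whose call did not change moved too: zinc finger genes to 18.4, and CCR4-NOT subunits, housekeeping, cell cycle and stress response genes to 76.4 to 97.47. The mitochondrial list gave 2.58 at p at or under 1e-05 and 2.35 for peaks found in both libraries. For peaks found in both libraries, other decay factors reached 98.5 and zinc finger genes 98.8, and zinc finger genes with at least 50 reads reached 98.7. Each library alone gave zinc finger genes 95.6 to 99.5. The other 81 results for lists kept their call or lack of one. Of peaks with 3 to 4 reads, 33.7% and 27.7% overlapped a peak of the other library.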

Other observations

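The tests on CNOT7 and the comparison of triplets beginning with GA were chosen only after the results were seen. The other tests were set before the values they measure were seen. The series has a single group, so no biological explanation was tested against another group.

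The Pumilio element and sites of the miR-101, miR-92 and miR-17 families were more frequent at 3′ UTR summits. Base and dinucleotide content of the captured fragments would give shuffled windows the motifs as often. The lowest lower bound of the ratio against dinucleotide-preserving shuffles was 6.86 for the Pumilio element, which argues against it for that element. For the microRNA sites it was 1.54, which met the limit set beforehand, a lower bound above 1. That limit cannot decide, since the poly(A) signal, not more frequent at summits than elsewhere in the UTR, also exceeded shuffles. It was called more frequent there, with a mean ratio of 1.95. The miR-1 site had a mean ratio of 2.62 against shuffles but was not called. A preference for the bases of the Pumilio element in any order is argued against as well. Of 200 random orders of its letters, 0 had a ratio as high in either library. The highest other order, GUANAUAU, is the element moved by 1 base and reached 7.25 and 5.86. A hypothesis that was not tested is that Pumilio proteins bound these RNAs next to the captured positions. A library from cells without these proteins would test it, and the series holds none.

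Summits were rich in G, poor in C and held more arginine codons. If base content of the fragments were the cause, the triplets CGG, CGA and AGG would be as enriched out of frame, and the largest out-of-frame difference was 2.73 points, above the in-frame 1.41 of the same library. This held at 1 base after the codon start, while the differences at 2 bases, 1.05 and 1.16 points, lay below the in-frame 1.27 and 1.41. As ratios to the control share the values were 1.44 and 1.48 in frame, 1.49 and 1.58 at 1 base and 1.27 and 1.31 at 2 bases. Single arginine codons did not move together. In frame, CGC had ratios of 0.776 and 0.805, while the others lay above 1, up to 1.64 for AGG in replicate 2. The glycine codon GGA had higher ratios than any of them, 1.81 and 1.82. A bias that acts on every RNA region would lower C outside 3′ UTRs and CDS too, and C was lower in 5′ UTRs and in non-coding RNA genes, with a highest upper bound of -1.41 points. Both technical explanations therefore stay open, and the codon values may reflect base content without any role of arginine. Triplets beginning with GA differed from this: they were more frequent at summits in frame by 6.57 and 7.04 points, above the 1.71 and 1.67 points at 1 base after the codon start and the 3.21 and 3.33 points at 2 bases. As ratios the frames lay closer together, at 1.58 and 1.61, 1.52 and 1.51, and 1.46 and 1.49.

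Peaks of CNOT7 lay in its coding sequence. It was compared with 37 other genes that had at least 500 coding reads in each library and untranslated regions making up at least 50% of their length. Among these it had the lowest share of untranslated reads in both libraries, at percentile 2.63, with upper bounds of 1.24% and 0.229% below the lower bounds of every other gene compared, 1.87% and 2.42% or more. Without the condition on length, 17 and 20 of the other 108 genes had shares as low. All of these had untranslated regions under 50% of their length, against 87.6% for CNOT7. A low share can follow from that alone, so they cannot show whether the pattern of CNOT7 is shared. The condition and the test were set after the low share of CNOT7 was seen, so the preference for coding sequence that abundant RNAs share stays open as the cause. Another candidate explanation is an RNA that holds the CNOT7 coding sequence without its untranslated regions, such as an introduced gene switched on by doxycycline. It was drawn from these same values, so they cannot test it, and it stays open too. The labels name no introduced gene, and use of a shorter 3′ UTR was not tested.

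Other values belong to no comparison. Reads in replicate 1 were 0.953 times those in replicate 2 over all peaks, but 1.696 times for MT-RNR2, 1.55 for MT-RNR1, 2.10 for MT-CO1 and 1.88 for AL669831.3. Of the reads of AL669831.3, 74.9% and 73.6% lay on mitochondrial pseudogenes annotated on the other strand. The 3′ UTR regions with the most reads in both libraries, chosen after their values were seen, included TMEM107 (chromosome 17, 8173446 to 8173557) with 475 and 418 reads, on SNORD118. MTRNR2L8 (chromosome 11, 10507893 to 10507964), a nuclear gene similar in sequence to MT-RNR2, had 649 and 414. Others that overlapped no small RNA gene were ATF4 (chromosome 22, 39522624 to 39522680) with 239 and 278, BBC3 (chromosome 19, 47220875 to 47220982) with 229 and 344, and TSPAN3 (chromosome 15, 77046041 to 77046148) with 229 and 269. Small RNA genes lay under 0.108% and 0.0846% of 3′ UTR peaks.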
